A study of Oryza sativa with 52 samples.

How the data were processed

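Leaf RNA of field-grown rice was measured in 52 samples, 13 sampling times in each of 4 plantings, on 26 Agilent two-colour arrays with a different sample in each channel. The plantings were sown and transplanted on different dates, so plant age and planting season differ together. The 77d and 69d samples of a time shared 1 array and the 56d and 42d samples shared another array of the same slide. The dyes were exchanged between times, with 77d in Cy3 at 7 times and in Cy5 at 6. Each of 7 slides held the samples of 1 or 2 sampling times, and the slide of 10:00 on day 9 was scanned in a separate session, per the file headers.

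Per the file headers, the scanner images were read with Agilent Feature Extraction 10.5.1.1, which gave for each spot a mean intensity, a median background intensity, a processed intensity after background subtraction and dye normalization, and flags of 0 or 1. The deposited series matrix holds log2 values. Compared with the scanner values, these follow the log2 of the processed intensities with the 52 channels brought to about the same median. Each column correlated more with its own channel (r of at least 0.997, across probes) than with the other channel of its array (at most 0.995). Column medians were all 6.10. The submitters' processing notes name the affy package without a version; its settings are not given in the sources used here.

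Each file held 156732 spots, of which 4854 were controls and 151878 rice probes. Mean spot and median background intensities were read with R 4.3.3 and its package data.table (version 1.17.8), corrected by the normexp method with an offset of 50, and normalized in limma 3.58.1 by loess within arrays, with controls at weight 0, and by Aquantile between arrays. Each sample's value is the log2 intensity of its own channel. The 245 probes with an outlier flag were left out, and averaging probes of the same sequence removed 3027 more, which left 148606 probes. A probe was tested if it was well above background in at least 13 of 52 samples, as 89774 were; 68451 of them were so in all 52. Median background was 17 to 21 in Cy3 and 63 to 71 in Cy5. Spots of the same sequence on 1 array differed with an SD of 0.17 log2, over 1950 sequences. The dye effect had a median size of 0.07 log2.

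For the daily rhythm, the 4 samples of each sampling time were averaged, since they share hour, weather and slide, and limma (lmFit and eBayes with trend) tested a cosine and sine pair of period 24 h over the 13 means. For planting age, limma fitted the 52 samples with planting, sampling time and dye as terms and array as a random block (statmod 1.5.0), with a correlation of 0.168 estimated on 5000 randomly drawn probes, and tested 42d against 77d and each pair of neighbours. For differences in the daily curve, planting by cosine and sine terms were added and tested together, with an array correlation of 0.137. The 8 samples of 10:00 were fitted with planting, dye and day. Benjamini-Hochberg adjusted p under 0.05 was the threshold, and such probes are called. These choices, the filter and the alternatives were fixed before the data were examined, except where the text says otherwise.

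The plantings are paired by the sampling times that the labels give. This was checked on the deviations of each sample from its planting mean: samples of the same time correlated at 0.621 or more, and 49 of 52 correlated best with another sample of their own time. Over all probes, samples correlated at 0.811 to 0.996.

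Named probes follow a fixed rule: for the planting comparisons, called probes with the same sign at all 13 times that have the highest or lowest log2 difference; for the rhythm, the widest swing; for differing curves, the smallest p; for 10:00, the highest and lowest called. The rule was written for genes with a name. Since the files do not pair probe identifiers with gene names and 0 of 148606 probe names matched the table of 39387 genes, it was applied to probes, 2 per direction, and only to probes well above background in every sample compared. The restriction to such probes, the minimum of 7 of 13 samples for a probe seen in 1 planting, the division of rhythmic probes into day and night peaks and that of differing curves by swing were set after the files were examined. Folds against a planting never well above background are lower bounds, set against the lowest level that counted as well above background in each sample. Planned gene lists and the gene summary were not run for want of names.

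Each procedure was tested on simulated data, 200 probes changed among 89774. The simulated noise was independent between samples, with each probe's residual spread from the fit that holds sampling time. It had no variation shared by a sampling time, slide or array, so the rates below hold only for such noise. At a true size of 0.5, 1 and 2 log2, the rhythm test recovered 68.7%, 95.5% and 100%, with 6 false calls and a median peak error of 0.152 h. The 42d against 77d test recovered 86.6%, 94.0% and 100%, with 11 false calls. The test of differing curves recovered 13.4%, 68.7% and 95.5%, and the 10:00 test 0%, 4.48% and 86.4%.

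Alternatives were processed intensities scaled to their 75th percentile, quantile normalization, the deposited log2 values, no background subtraction, other filters, no array block, no dye term, a 24 h curve in place of the sampling time block, times of 1 dye orientation only, slides, times or plantings left out, slide as a block, other curve shapes and another spread. Leaving out 4 times, those with the lowest slopes of a neighbour difference on its mean over the other times, and adding planting by dye terms were chosen after seeing the data. Labels were regrouped at most 99 times per result with a fixed seed. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. Control spots were left out of the tests.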

Results

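RNA was measured in 52 leaf samples of field-grown rice, Oryza sativa, of the japonica variety Koshihikari, from a paddy field at Tsukuba in Japan. The samples came from 4 plantings, labelled 77, 69, 56 and 42 days from transplanting to sampling and written here as 77d, 69d, 56d and 42d. Each planting was sampled at the same 13 times over 78 h, from 04:00 on day 6 of August to 10:00 on day 9, at intervals of 6 or 8 h. The labels report ordinary cultivation with no treatment, and the series design states that no time point was replicated. The p-values below therefore rest on the spread between sampling times of 1 planting each, and say nothing of how plots of the same age vary. Two-colour arrays of 60-base probes carried 2 samples each, so 26 arrays on 7 slides held the 52 samples. Of 148606 probes, 89774 were well above background in at least 13 samples and were tested. Between 52.3% and 60.5% of the probes were well above background in any 1 sample, and 0 spots were saturated. The number of arrays limits the precision. The files do not pair probe identifiers with gene names, and 0 of the 148606 probe names matched the table of 39387 genes used here, so probes are named with their sequences.

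Sampling time was the largest source of variation in leaf RNA in these samples, followed by planting. The sampling times can differ in day, weather and slide as well as in clock hour, and no share was computed for clock hour alone. Sampling time took 78.2% of the sum of squares over the tested probes, planting 12.5% and the remainder after both and the dye 8.62%. The first 2 principal components, with 41.5% and 25.1% of the variance, arranged the samples in a ring by clock hour. The third, with 11.7%, separated the older plantings from the younger ones. Its mean score was 88.7 ± 23.0 in 77d and 26.74 ± 21.5 in 69d, against -60.4 ± 23.3 in 56d and -55.0 ± 26.8 in 42d (SD over sampling times, n = 13 each). The 77d and 69d samples shared arrays with each other and never with the 56d and 42d samples, so this split also follows the arrays.

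**Figure D1:**
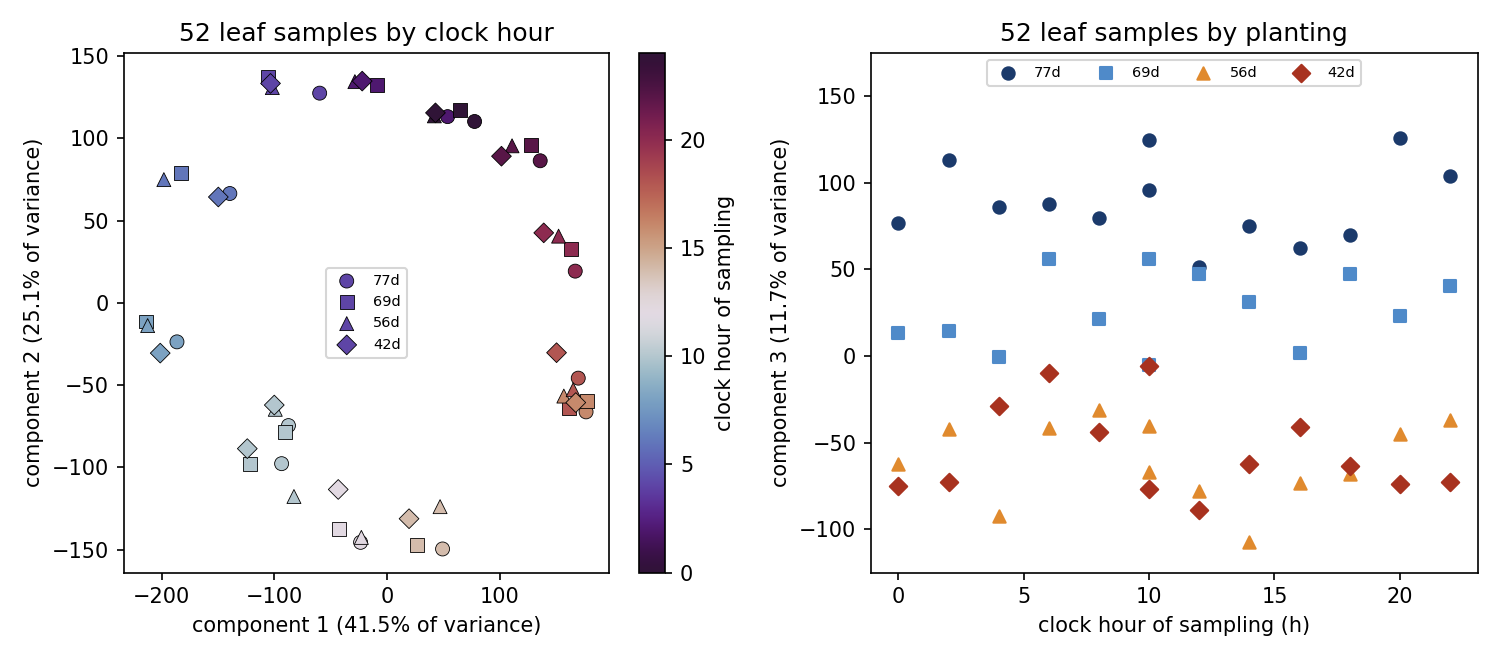
Principal component scores of the 52 leaf samples, 1 point per sample and 1 shape per planting. On the left, components 1 and 2 place the samples in a ring by clock hour (colour, in hours); on the right, component 3 is plotted against clock hour, with 77d averaging 88.7 and 56d averaging -60.4.

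The series describes itself as a record of diurnal variation, and the first comparison asked which probes followed a 24 h curve. Most did: 69846 of the 89774 tested probes (77.8%) fitted a 24 h cosine curve, and 32847 (36.6%) did so with a fitted swing of at least 2-fold from trough to peak. The swing reached at least 4-fold at 10866 probes and at least 16-fold at 1929. The widest swings, looked up separately for peaks by day and by night, belonged to probes near the bright end of the scale at one hour and near its dim end at another. Probe eAry2_46213 (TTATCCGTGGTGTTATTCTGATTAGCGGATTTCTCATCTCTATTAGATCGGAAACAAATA) peaked at a fitted 12.0 h, with a mean log2 intensity of 16.55 ± 0.37 at 14:00 on day 8 and 6.97 ± 0.13 at 00:00 on the same day (SD over 4 plantings). Probe eAry2_38876 (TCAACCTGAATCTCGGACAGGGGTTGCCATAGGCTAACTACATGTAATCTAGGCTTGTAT) peaked at a fitted 3.53 h, with 16.61 ± 0.12 at 04:00 on day 6 and 6.89 ± 0.11 at 18:00 on day 7.

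The fitted swing was 10.81 ± 1.18 log2 at eAry2_46213 (SE over 13 sampling times, limma adjusted p = 1.39e-05) and 10.18 ± 0.54 at eAry2_38876 (adjusted p = 1.07e-07). A fitted cosine can swing wider than the values themselves, as it did at both probes. At eAry2_46213 the values formed a daytime plateau, and the fitted peak hour is near its middle. In 77d they were 16.07 at 06:00 and 16.45 at 12:00 on day 7, and 15.99 at 16:00 on day 6. The next widest swings came from 44kb3_38952, with 10.74 ± 1.14 log2 and a peak at 12.0 h (adjusted p = 1.12e-05), and 44kb3_2161, with 10.05 ± 0.56 and a peak at 3.58 h (adjusted p = 1.44e-07). These are not independent transcripts by sequence: 44kb3_38952 shares a stretch of 20 bases with eAry2_46213, and 44kb3_2161 shares 38 bases with eAry2_38876. Over the 69846 called probes the median swing was 0.95 log2, and the curve took a median fraction of 0.784 of the variance between sampling times.

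Peaks of the 32847 probes with at least a 2-fold swing gathered around dawn and around the late afternoon and dusk. From 06:00 to 18:00, 17300 peaked (52.7%), and the other 15547 peaked between 18:00 and 06:00. The fullest 2 h bins were 16:00 to 18:00, with 4335 probes, and 06:00 to 08:00, with 4250. The emptiest were 12:00 to 14:00, with 1456, and 02:00 to 04:00, with 1658. In windows chosen after the distribution was seen, 7438 probes (22.6%) peaked from 04:00 to 08:00 and 11008 (33.5%) from 14:00 to 20:00. The test was limma's moderated F-test of a cosine and sine pair on the means of the 4 plantings at each of the 13 times. With slide as a fixed block, which leaves only comparisons between the 2 times of a slide, 37081 probes were called.

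**Figure D2:**
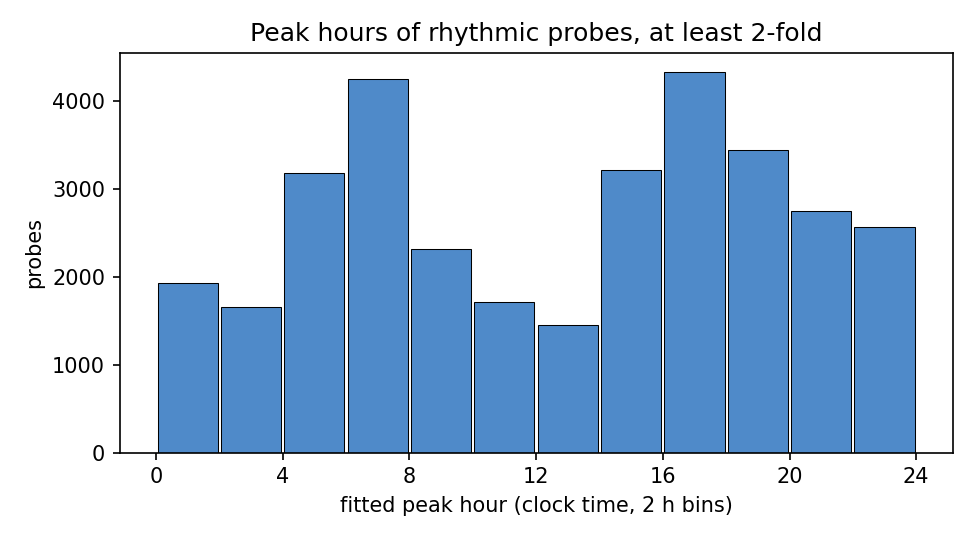
Number of probes by fitted peak hour in 2 h bins of clock time, for the 32847 probes that fitted a 24 h curve with a swing of at least 2-fold. The fullest bins are 16:00 to 18:00 (4335 probes) and 06:00 to 08:00 (4250 probes).

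The next comparisons asked how leaf RNA differed with planting age at matched times of day, beginning with the youngest planting against the oldest. Probe 44kb3_25341 (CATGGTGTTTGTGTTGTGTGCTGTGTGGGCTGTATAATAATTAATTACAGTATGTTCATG) was higher in 42d than in 77d, at a mean log2 intensity of 14.23 ± 1.49 against 8.37 ± 0.86 (SD, n = 13 each), a difference of 57.7-fold. Probe eAry1_32906, which shares 57 bases with it, was 54.1-fold higher. In the other direction, eAry1_14244 (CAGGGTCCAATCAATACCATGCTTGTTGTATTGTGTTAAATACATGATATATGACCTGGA) stood at 8.23 ± 0.77 in 42d against 13.03 ± 0.58 in 77d. PPNTpc_00175 (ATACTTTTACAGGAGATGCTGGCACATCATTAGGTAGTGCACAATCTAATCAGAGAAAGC) stood at 10.74 ± 1.26 against 15.09 ± 0.46. Each of these 4 probes kept its direction at 13 of 13 sampling times, which the rule for naming probes required in every planting comparison.

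Between 42d and 77d, 51741 probes (57.6%) were called, 23634 higher in 42d and 28107 lower. Of these, 5121 differed by at least 2-fold, with 2551 higher and 2570 lower in 42d. The balance and the number of large differences depended on the values used. With processed signals scaled to their 75th percentile, 26972 probes were higher and 23811 lower, of which 5652 and 4291 by at least 2-fold. With the deposited series matrix values, 4715 and 3864 were at least 2-fold higher and lower. Quantile normalization, which kept the main background correction, gave 2660 and 2508, close to the main counts. No background subtraction gave 2762 and 2789. The same sign at all 13 times was found at 18582 called probes. A further view is of probes never well above background in one planting but so in at least 7 of 13 samples of the other. There were 432 such called probes seen in 42d and not in 77d, the largest difference being at least 10.7-fold. Another 168 were seen in 77d and not in 42d, the largest difference being at least 4.38-fold. Of the 5121 probes at least 2-fold apart, 222 were never well above background in one of these plantings. Most of the 432 and 168 thus differed by less. The log2 differences of the 4 named probes were 5.85 ± 0.32 (SE, limma adjusted p = 1.77e-17), 5.76 ± 0.32 (3.13e-17), -4.78 ± 0.29 (2.09e-16) and -4.35 ± 0.32 (2.4e-14), in the order above. Of the probes that differed by at least 2-fold on the other slides, between 97.0% and 99.9% had the same sign on the slide left out, over the 7 slides. The 42d and 77d samples were never on the same array. In the contrasts between plantings that shared an array, 69d less 77d plus 42d less 56d, the called probes showed 0.446 ± 0.298 of the difference (mean share and SD over sampling times, above 0 at 13 of 13). The rest lies between 56d and 69d, where planting and array position on the slide cannot be told apart.

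**Figure D3:**
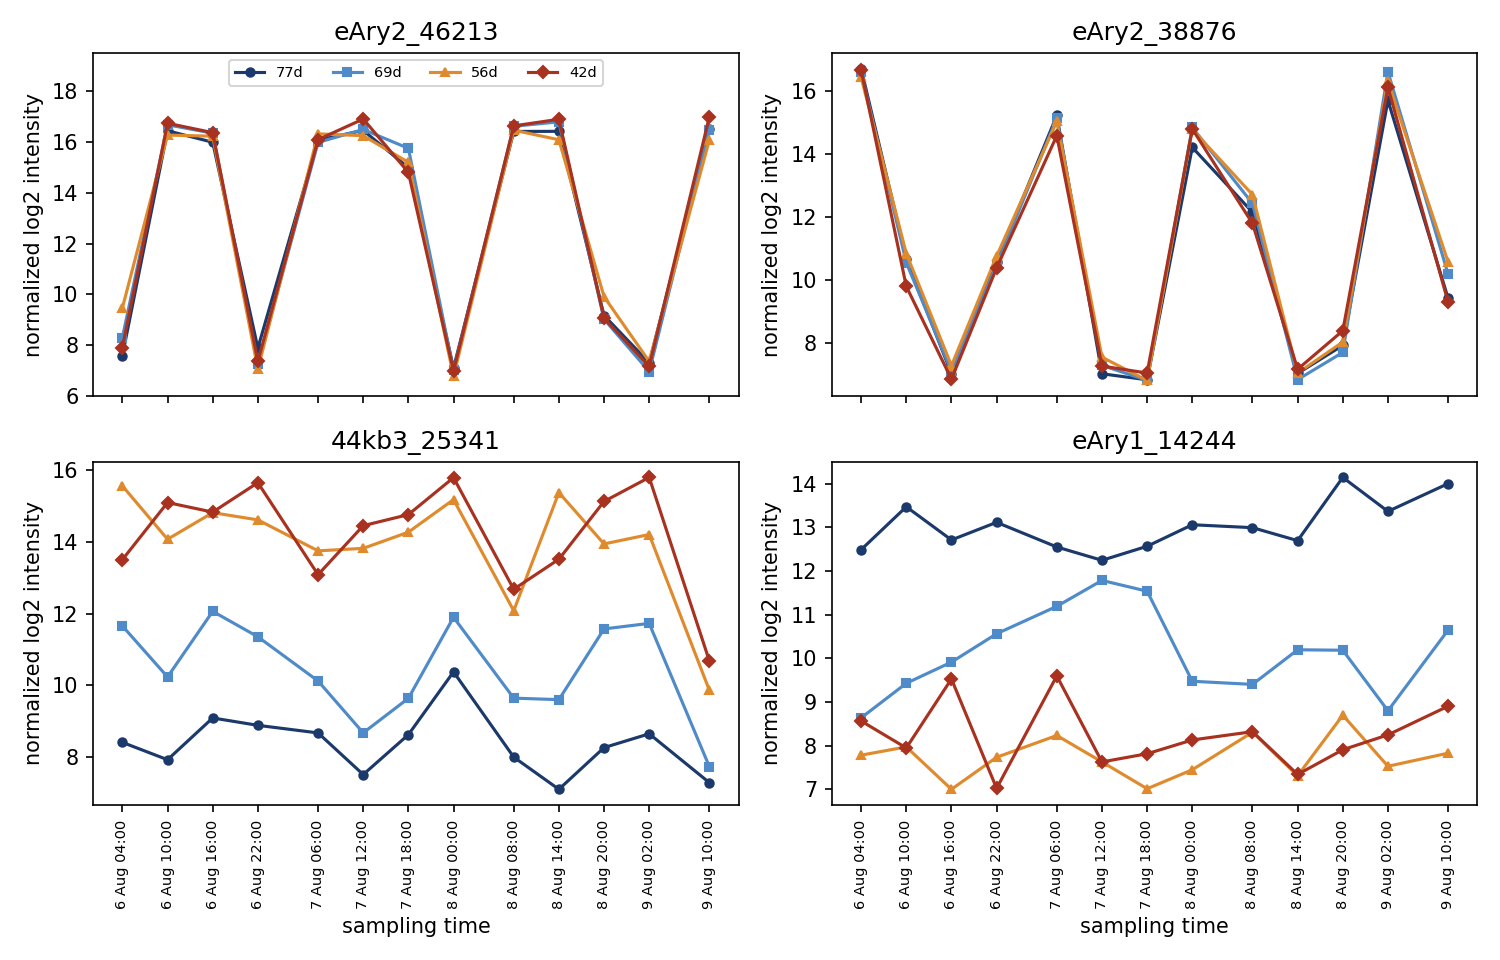
Normalized log2 intensity of 4 named probes at the 13 sampling times, with 1 line per planting and 1 sample per point. The upper probes swing with clock hour in the 4 plantings. Probe 44kb3_25341 is higher in 42d than in 77d at 13 of 13 times, and eAry1_14244 is lower at 13 of 13. The lower probes were chosen among those with the same sign at all 13 times.

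The remaining comparisons set neighbouring plantings side by side. Between 69d and 77d, probes that differed by at least 2-fold were mostly lower in the younger planting, 888 lower against 152 higher. Probe eAry1_14244 stood at 10.13 ± 0.99 in 69d against 13.03 ± 0.58 in 77d, 7.30-fold lower. Probe 44kb3_35956 (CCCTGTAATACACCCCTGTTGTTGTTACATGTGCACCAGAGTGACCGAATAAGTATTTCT) was 7.24-fold lower. The overlapping pair 44kb3_25341 and eAry1_32906 was higher in 69d by 4.22-fold and 4.13-fold.

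In all, 35814 probes (39.9%) were called between 69d and 77d, 16384 higher in 69d and 19430 lower. The share of higher probes, 45.7%, depended on the scaling: it was 56.2% with processed signals scaled to their 75th percentile, 57.7% with quantile normalization and 57.9% with the deposited series matrix values. Among probes that differed by at least 2-fold, more were lower than higher under each of these 3, with 1878 lower and 760 higher, 823 and 163, and 1619 and 673 in the same order. They were 628 lower and 97 higher without slide 7 (20:00 on day 8 and 02:00 on day 9), and 1487 and 211 without 4 times chosen after the data were seen, 04:00 on day 6 and 06:00, 12:00 and 18:00 on day 7. The log2 differences were -2.87 ± 0.26 at eAry1_14244 (SE, limma adjusted p = 2.36e-10), -2.86 ± 0.33 at 44kb3_35956 (2.03e-08), 2.08 ± 0.29 at 44kb3_25341 (5.29e-07) and 2.05 ± 0.29 at eAry1_32906 (7.87e-07), each with the same sign at 13 of 13 times. Of the probes that differed by at least 2-fold on the other slides, 85.8% kept their sign on the slide of 06:00 and 12:00 on day 7, and 98.6% to 100% did on each other slide. With only the 6 times that had 77d in Cy5, which include 12:00 and 18:00 on day 7, 11911 probes were called, 528 of them at least 2-fold lower and 96 higher. With only the 7 times that had it in Cy3, 36484 were called, 1349 and 246 in the same order.

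Between 56d and 69d, more of the larger differences were upward in the younger planting, with 1053 probes at least 2-fold higher in 56d and 681 lower. Probe eAry1_24857 (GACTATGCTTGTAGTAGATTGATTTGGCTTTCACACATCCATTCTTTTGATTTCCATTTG) stood at 11.39 ± 1.17 in 56d against 7.64 ± 0.90 in 69d, 13.4-fold higher. Probe 44kb3_25341 was 11.5-fold higher. Probe eAry2_14542 (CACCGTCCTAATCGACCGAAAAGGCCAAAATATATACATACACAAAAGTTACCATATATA) stood at 7.63 ± 0.79 against 11.14 ± 0.54, 11.5-fold lower, and PPNTpc_00175 was 8.14-fold lower.

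The called probes numbered 33343 (37.1%), 16257 higher in 56d and 17086 lower; the balance was 14498 and 19268 with quantile normalization and 12557 and 17961 with the deposited series matrix values. At least 2-fold apart were 2943 higher and 1743 lower with processed signals scaled to their 75th percentile, and 2367 and 1630 with the deposited series matrix values. Seen in 56d and never well above background in 69d were 182 called probes, the largest difference being at least 10.3-fold. The reverse held for 57, the largest difference being at least 2.16-fold. Among probes at least 2-fold apart, 54 were never well above background in one of these plantings. Most of the 182 and 57 thus differed by less. The log2 differences were 3.75 ± 0.38 at eAry1_24857 (SE, limma adjusted p = 1.29e-09), 3.52 ± 0.32 at 44kb3_25341 (1.64e-10), -3.53 ± 0.20 at eAry2_14542 (1.25e-14) and -3.03 ± 0.32 at PPNTpc_00175 (2.69e-09), with the same sign at 13 of 13 times. By slide, 96.0% to 100% of the 2-fold probes kept their sign. The samples of 56d and 69d were never on the same array, and the count fell to 15806 when a 24 h cosine and sine pair replaced the sampling time block, which pairs the plantings by time. It was 17889 without 4 times, 04:00 on day 6 and 06:00, 12:00 and 18:00 on day 7. At these, the difference of another pair of neighbours had its lowest slopes on its mean over the other times.

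Of the comparisons between plantings, that of the 2 youngest had the fewest probes at least 2-fold apart. Of its 258, 144 were higher in 42d than in 56d and 114 lower. Probe 44kb3_37444 (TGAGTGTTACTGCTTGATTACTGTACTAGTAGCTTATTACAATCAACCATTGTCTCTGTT) stood at 10.77 ± 1.26 in 42d against 8.29 ± 1.01 in 56d, 5.56-fold higher, and eAry2_28303 was 4.76-fold higher. Probe 44kb3_10988 (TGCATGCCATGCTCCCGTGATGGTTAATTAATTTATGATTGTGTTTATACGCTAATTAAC) stood at 10.30 ± 0.82 against 12.75 ± 0.45, 5.47-fold lower, and 44kb3_16292 was 5.45-fold lower.

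Between 42d and 56d 12768 probes (14.2%) were called, 6230 higher in 42d and 6538 lower. At least 2-fold apart were 467 higher and 235 lower with processed signals scaled to their 75th percentile, and 439 and 216 with the deposited series matrix values. The log2 differences were 2.47 ± 0.25 at 44kb3_37444 (SE, limma adjusted p = 7.12e-09), 2.25 ± 0.28 at eAry2_28303 (3.8e-07), -2.45 ± 0.13 at 44kb3_10988 (2.45e-16) and -2.45 ± 0.13 at 44kb3_16292 (1.2e-16), with the same sign at 13 of 13 times. By slide, 88.5% to 100% of the 2-fold probes kept their sign. The count was 7983 without slide 3 (16:00 and 22:00 on day 6) and 7474 without slide 5 (18:00 on day 7 and 00:00 on day 8). It was 6558 without the 4 times of lowest slopes, 04:00 on day 6 and 06:00, 12:00 and 18:00 on day 7.

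**Figure D4:**
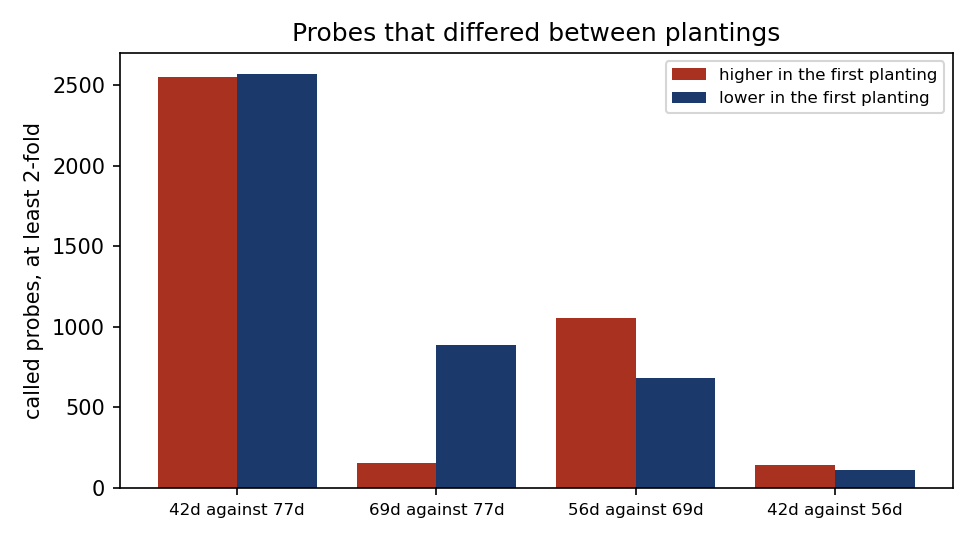
Number of called probes that differed by at least 2-fold between plantings, with bars for probes higher and lower in the first planting named. The oldest and youngest plantings differ at 2551 and 2570 probes, and the 2 youngest at 144 and 114.

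Whether the daily curve itself differed with planting age was asked next. It did at 12646 probes (14.1%), where the size or the timing of the 24 h curve differed among the 4 plantings. Probe eAry1_41388 (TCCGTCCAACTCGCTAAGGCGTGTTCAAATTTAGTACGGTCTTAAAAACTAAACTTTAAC) peaked at 23.9 h in 77d and near midday in the others, at 13.0 h in 69d, 12.9 h in 56d and 11.2 h in 42d. Its fitted swing was 2.01 log2 in 77d, 0.84 in 69d, 1.94 in 56d and 1.12 in 42d. Probe eAry2_22599, which shares 34 bases with it, peaked near midnight in 77d, at 11.9 h in 69d, 12.7 h in 56d and 10.7 h in 42d. Probe eAry1_10303 (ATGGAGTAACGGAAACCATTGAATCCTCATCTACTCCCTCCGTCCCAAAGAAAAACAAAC) kept its morning peak, at 9.11 h in 77d and 8.54 h in 42d, while its swing was 1.89 log2 in 77d, 2.75 in 69d, 3.16 in 56d and 3.28 in 42d. Probe 44kb3_6098 peaked at 15.7 h in 77d and 14.5 h in 42d.

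The test was limma's moderated F-test of planting by cosine and sine terms, with adjusted p = 1.57e-06 for eAry1_41388 and eAry2_22599, 6.95e-06 for eAry1_10303 and 1.11e-05 for 44kb3_6098. These are the probes of smallest p with a smaller and with a larger swing in 42d than in 77d, a division made after the values were seen. Of the called probes, 5818 were bright in every sample and had a shared swing of at least 2-fold. Among them 2921 had a smaller swing in 42d than in 77d and 2897 a larger one, with a median absolute difference of 0.38 log2. The peak was over 1 h apart between these plantings at 2126 of the 5818 probes, earlier in 42d at 1592 and later at 534. The count of 12646 was 4075, 5088, 3700 and 4455 without slides 4, 5, 6 and 7, which hold the times from 06:00 on day 7 to 02:00 on day 9, and 3464 without the 4 times of lowest slopes. It was 8340 with no filter on dim probes, 8271 with no dye term and 3185 when a day against night difference replaced the curve. Under the last of these, eAry1_10303 was not called. The fall without the 4 times of lowest slopes was not particular to them. In 20 random draws of 4 other times left out, the median count was 1166, against 3586 at the same fixed array correlation.

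The last comparison set the 1 clock hour sampled on 2 days, 10:00 on day 9, against 10:00 on day 6. The correlation across probe means, where probes are not independent replicates, was 0.990. It was 0.984 between 10:00 on day 6 and 12:00 on day 7, the time nearest to it apart from 10:00 on day 9. The median absolute difference was 0.15 log2 between the 2 days at 10:00, against 0.20 log2 between those 2 hours. Of 288 called probes (0.321%), 48 were higher on day 9 and 240 lower. The balance was 3928 and 4753 with the spread taken from all 52 samples, and 414 and 546 without 56d. Probe eAry2_21483 (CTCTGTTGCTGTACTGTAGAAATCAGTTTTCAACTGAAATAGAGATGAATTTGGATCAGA) stood at 11.14 ± 0.65 on day 9 and 8.30 ± 0.28 on day 6 (SD, 4 plantings each), 7.16-fold higher, and 44kb3_15967 was 5.42-fold higher. Probe eAry2_07384 (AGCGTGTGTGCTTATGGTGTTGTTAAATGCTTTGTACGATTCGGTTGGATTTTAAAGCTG) stood at 8.94 ± 0.20 and 12.20 ± 0.43, 9.55-fold lower, and 44kb3_18331, which shares 40 bases with it, was 8.85-fold lower.

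The log2 differences were 2.84 ± 0.20 at eAry2_21483 (SE, limma adjusted p = 0.0476), 2.44 ± 0.14 at 44kb3_15967 (0.0476), -3.26 ± 0.26 at eAry2_07384 (0.0493) and -3.15 ± 0.26 at 44kb3_18331 (0.0493), each at the edge of the threshold. Called probes numbered 0 without 69d or without 42d (limma), where 8815 and 7699 had an unadjusted p under 0.05. They numbered 1632 without 77d and 960 without 56d. The fit of 8 samples left few residual degrees of freedom to estimate the spread, and leaving out a planting left fewer. These counts therefore do not show whether the difference rests on any of the plantings. The 10:00 samples of the 2 days were on different slides, and that of day 9 was scanned in a separate session, so day and slide cannot be told apart.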

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

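The tests of sample labels, of afternoon hours, of slide and scan session at 10:00, of planting by dye terms and of 4 times left out were chosen after the results were seen, and those 4 sampling times were picked from the data.

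The difference in daily curves between plantings stands out, since 12646 probes had a 24 h curve that differed among the 4 plantings. A dye bias that differs between plantings would account for it only if calls fell once such a bias was modelled, but 14978 probes were called with planting by dye terms added. The 4 times with the lowest slopes of a neighbour difference on its mean may contribute but are unlikely to be the whole cause. Without them 3586 probes were called at a fixed array correlation. In 20 draws of 4 other times left out, the median was 1166 and the range 362 to 11926. Of these 20 draws, 15 called as few probes or fewer. Among 100 arrangements of the planting labels within times, the real one included, 1 gave as many calls, and the highest of the others was 1. The arrangements were made after planting means and the dye effect were taken out. Labels that are interchangeable at each time are thus excluded. Departures that a planting keeps over neighbouring times or on 1 slide are broken up by the arrangements, so these cannot exclude them. Planting age and season stay open, untested, and the count falls to 3700 without slide 6.

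At 12:00 and 18:00 on day 7, the differences of 69d from 77d were the smallest of the 13 times (SD over probes 0.19 and 0.26 log2), and their slopes across probes on the mean difference of the other times were 0.236 and 0.321, against a mean of 1.08 ± 0.375 at the other 11 times (SD; range 0.568 to 1.80). Exchanged labels would give a slope near -1 and are excluded by the lower of the 2, 0.236. A 77d leaf sample under the 69d label predicts a slope near 0, and both slopes lie within 1 SD of it, so this stays open. So does a real similarity in the afternoon: the other times from 12:00 to 18:00, 16:00 on day 6 and 14:00 on day 8, had the next lowest slopes, 0.716 and 0.568, with a mean of 0.642 against 1.17 ± 0.342 at the remaining 9 times (SD), and the next smallest differences. For 42d against 56d, the slopes were also low, 0.273 at 04:00 on day 6 and 0.149 at 06:00 on day 7, against 0.830 ± 0.239 at the other 11 times. The differences there were not small but of another direction, with an SD over probes of 0.42 log2 at both times. It was 0.34 ± 0.08 at the other 11 times and 0.19 at the least between plantings on 1 array. Leaves of 1 planting under both labels stay open there. No time was replicated, so the spread between leaf samples of 1 planting was not measured.

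The differences at 10:00 between day 9 and day 6 could come from the slide and its scan session as well as from the day, and these cannot be told apart because 0 slides held 10:00 samples of both days. Of the 7 splits of these 8 samples by day that could be fitted, 1 gave as many calls, the real one with 288, and the highest of the others gave 0 (limma); the splits are too few for a share under 0.05. At an unadjusted p under 0.05, 16839 probes differed in the real split. The day itself was not tested apart from the slide.

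Control probe ETG10_236652, which belongs to no comparison, was picked as the control farthest above the negative control. It lay 0.41 log2 above, at 6.43 ± 0.10 against 6.02 ± 0.03 (SD, n = 52), and was above it in 52 of 52 samples. Other controls were also above it in 52 of 52, such as ERCC-00028_121 by 0.16 log2. Among 16 sets of 4 samples at the extreme or compared times of named probes, 2 had a sample far from the others, where chance gives about 1 in 20. For eAry2_38876 at 18:00 on day 7, the gap took 0.908 of the range, with 42d at 7.06 log2 and the other 3 at a mean of 6.83 ± 0.01. For 44kb3_2161 at 04:00 on day 6, it took 0.865 of the range, with 56d at 16.12 and the other 3 at 16.38 ± 0.02. The 4 samples of each set come from 4 plantings, not from 1 group.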

How the results depend on the processing

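Leaving out 4 times and adding planting by dye terms were chosen after seeing the data. No named probe of the rhythm, the planting comparisons or 10:00 reversed. For differing curves, direction was not checked. The count of called probes for 42d against 77d stayed within 1.5 times under its 19 alternatives (35214 to 54286). The lowest, 35214, came from the times with 77d in Cy5, where dye and planting coincide. Counts of probes at least 2-fold apart depended more on the values used. For 42d against 77d, 2551 were higher and 2570 lower. With scaled processed intensities these were 5652 and 4291. With quantile normalization, which kept the main background correction, they were 2660 and 2508. Rhythmic probes numbered 37081 with slide as a fixed block, where only contrasts within slides remain. With a cosine and sine pair in place of the sampling time block, the pairing by time, 56d against 69d called 15806 probes, and no other count moved by over 1.5 times. Only the times with 77d in Cy5 gave 11911 for 69d against 77d, where dye and planting coincide as well. Without the 4 times of lowest slopes, 17889 were called for 56d against 69d, 6558 for 42d against 56d and 3464 for differing curves. Draws of 4 other times left out were made only for differing curves. Differing curves also gave 8340 with no filter on dim probes, 8271 with no dye term and 3185 as day against night, where eAry1_10303 lost its call. The 10:00 count was 704 with scaled processed intensities, 480 with quantile normalization, 654 with the deposited log2 values, 42 with no filter, 516 with the stricter filter and 8681 with the spread of 52 samples. Leaving out 1 slide gave 7474 (slide 5) to 11842 for 42d against 56d, with 7983 without slide 3, and 3700 to 12193 for differing curves, with 4075, 5088 and 4455 without slides 4, 5 and 7. Leaving out 1 planting gave 0 (69d or 42d) to 1632 (77d) at 10:00, and 960 without 56d; where 0 were called by limma, 8815 and 7699 had an unadjusted p under 0.05. The 10:00 fits without a planting left few residual degrees of freedom, so their counts do not show what a planting contributed. Apart from the constructions named, the cause was not tested. Named probes kept their call in 508 planned and 28 added checks and lost it in 12, of which 11 were at 10:00. Alternatives by gene summary could not be run. Probes not well above background limit what dim transcripts can show.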

Other observations

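The test of swing by regrouping and the array position tests were chosen after the results were seen.

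A hypothesis found in these data, and tested on them only in part, is that daily swings were slightly wider in the middle plantings. Over 26614 bright rhythmic probes with a swing of at least 2-fold, the median swing relative to the shared curve was 0.957 in 77d, 1.06 in 69d, 1.03 in 56d and 0.952 in 42d. The median fitted swing was 1.56, 1.71, 1.70 and 1.53 log2 in the same order. Peaks ran later than the shared curve by a median of 0.176 h in 77d and 0.0974 h in 69d, with -0.231 h in 56d and -0.0177 h in 42d, where a minus sign means earlier. Among 100 arrangements of the planting labels within times, 1, the real one, had as wide a range of relative swing, 0.104 against 0.0933 at most in the others (permutation p = 0.01, the smallest they can give). Such a range can be wide for any order of the 4 plantings, so it does not test the middle ones against the outer ones. The range of peak shifts was 0.407 h against 0.394 h at most (permutation p = 0.01). Background correction and normalization are unlikely to be the source, since under 4 other sets of values the middle plantings both stayed above the outer ones, by 0.0608 or more. With 1 planting per age, a difference between plots remains open.

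The overlap of planting differences and rhythm was counted but not tested. Of the 5121 probes at least 2-fold apart between 42d and 77d, 3737 were rhythmic, where 3984 would be by independence. The numbers were 751 and 809 for 69d against 77d, 1082 and 1349 for 56d against 69d, and 148 and 201 for 42d against 56d. Of the 12646 probes whose curves differed between plantings, 11197 were rhythmic, where 9839 would be by independence.

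The identifiers fall into 9 classes by their first letters, whose meaning the files do not give. The share of tested probes that was rhythmic ran from 71.4% in the class PPNTnpc, with 1275 tested, to 79.5% in 44kb3Koshi, with 224 tested. The share kept by the filter ran from 19.9% in Cuffnpc to 77.8% in 44kb3. The log2 ratio of Cy3 to Cy5 of the 10 spike-in controls varied over 26 arrays with an SD of 0.15 to 0.19.

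Each count of called probes was set against other arrangements of the same samples, 100 each with the real one included. In each case below only the real one reached its count, so hours or labels that are interchangeable from time to time are excluded. The arrangements do not keep what neighbouring times or the times of 1 slide share, so they cannot exclude effects of that kind. Shuffling the 13 sampling hours gave at most 19346 rhythmic probes against 69846. With slide as a fixed block, 37081 were called. Exchanging 2 planting labels at random times gave at most 45304 against 51741 for 42d and 77d, 31150 against 35814 for 69d and 77d, 23483 against 33343 for 56d and 69d, and 6925 against 12768 for 42d and 56d. Each of these 4 highest counts came from an arrangement that exchanged the labels at 1 of the 13 times or is the mirror of one, and the median of the other arrangements was 0 in each case.

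The position of the array on the slide stays open for 56d against 69d, since 0 arrays held samples of both plantings. For 42d against 77d the values argue against it as the whole cause. Position forbids a difference between samples of 1 array. Over the 51741 called probes, the contrasts within arrays, 69d less 77d plus 42d less 56d, held 0.446 ± 0.083 of the difference. This is the mean share with its SE over 13 sampling times, and the share was above 0 at 13 of 13. The bound in SE was set after the value was seen. A first bound, in SD over sampling times (0.298), decided nothing. The 13 shares are not independent, since each was set against a mean over the other slides. Nearly all of the share came from 69d less 77d, with 0.423 ± 0.188, against 0.0228 ± 0.205 from 42d less 56d (SD over sampling times). For the remainder of the difference, position stays open. The older plantings and the younger ones kept to different positions, so the split of older from younger samples on the principal component of planting age carries the same limit.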
